A study of Arabidopsis thaliana with 45 samples.

How the data were processed

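Leaf discs of Arabidopsis thaliana were profiled on Affymetrix expression arrays, with 45 arrays in 15 groups of 3 replicates. Groups, replicate numbers, times and treatments were taken from the sample labels. The labels do not state whether the replicates of a group were separate plants or separate experiments, so the p-values below measure only the spread between samples.

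The deposited values are log2 expression values per probe set, which the authors made with RMA per the labels; the RMA version and settings are not given in the sources used here. The distributions of 2 arrays, wild type 0 h replicate 2 and wild type flg22 2 h replicate 2, differed from those of the other 43, so a single normalization across all 45 columns was not assumed. No further normalization was applied for the main results. The number of arrays limits the precision. The protocol text attached to the samples describes a bacterial inoculation that the titles and the series description do not mention; groups were assigned from the titles and descriptions of the samples.

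The table held 22810 probe sets. After 64 control probe sets were left out, 22746 were tested. The annotation table listed 14016 probe sets, of which 503 named several genes and 13513 named 1 gene; 13436 of the latter carried a locus in the reference table. A further 8730 tested probe sets were not listed there and are described without a name.

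Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 45 arrays (lmFit, eBayes, 30 residual degrees of freedom). Each test was two-sided, with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of 0.05. There were 26 comparisons, each adjusted on its own. An interaction was the NAA effect with flg22 minus the NAA effect without it, and a response difference was the flg22 effect in a line minus that in wild type. The NAA effect without flg22 was NAA without peptide against inactive flg22, so the interaction also holds any effect of the inactive peptide. No mock of the solvent of NAA is labelled. The adjusted p-values in the text are from this model unless another test is named. In simulated data with known changes of 0.5, 1 and 2 on the log2 scale, the model recovered 14.9%, 62.7% and 93.9% of the changed probe sets in the layout of flg22 against inactive flg22 at 1 h. The same shares were 11.9%, 67.2% and 97% for NAA at 1 h, and 10.4%, 46.3% and 95.5% for 35S:AFB1 at 0 h. Of all calls in these simulations, 10 of 124, 5 of 122 and 4 of 105 were false. The simulated noise was independent and of the same spread on all arrays, without arrays of another distribution. These shares may therefore not hold for the real arrays.

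Before the data were examined, the comparisons, the tests, 20 gene lists and the rule for named genes were fixed. The rule took, for each comparison and from probe sets naming exactly 1 gene, the 8 largest rises and the 8 largest falls among those past the threshold whose 3 replicates of one group all lay above all 3 of the other. For interactions the threshold alone applied. In addition 15 genes were always to be named, of which 1, GH3.3, had a probe set with its name, and up to 4 passing members per list. A gene with several probe sets was read from the probe set with the highest mean. Where few probe sets were called, some unnamed probe sets are given as well; these were chosen after their values were seen.

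The lists held 286 entries, of which 36 had a probe set with their name. The 13 lists with a measured member were auxin response, early flg22 response, photosynthesis, salicylic acid, jasmonate, abscisic acid, cytokinin type-A regulators, tryptophan biosynthesis, indole glucosinolate, aliphatic glucosinolate, flavonoid, circadian clock and guard cell markers. The 7 lists without one were auxin receptors, camalexin, ethylene, heat shock, touch, vascular markers, and epidermis and trichome markers; these were not analysed here. Counts of members are over all probe sets tested and adjusted over the list alone; for a list with 1 measured member the latter is the unadjusted p. Lists with at least 3 measured members were compared with all other probe sets by limma's camera, with a preset correlation of 0.01 and with an estimated correlation; that minimum was set after seeing how few members were measured.

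The alternatives tried were a filter on dim probe sets (mean log2 of at least 5), a block for replicate number, a fit on the arrays of the compared groups alone, array weights (method genebygene), cyclic loess scaling, eBayes with trend and robust options, each array left out in turn, and the mean over all probe sets of a gene. For NAA, wild type 0 h as the control in place of inactive flg22 was tried as well. One alternative was added after seeing the data: a fit on 43 arrays, without the 2 arrays of another distribution. The effect of flg22 on the auxin response was further tested on list means by permuting the residuals of a fit without the interaction over the 12 arrays at 1 time; all arrangements were enumerated, but a permutation of residuals is approximate. For comparisons of 2 groups all other splits of the 6 arrays were counted, and for comparisons of 4 groups random permutations of the residuals of a fit without the interaction, over all their arrays and, added after seeing the data, within replicate numbers.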

Results

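The series asked how auxin signalling affects the response of Arabidopsis leaves to flg22, a peptide from bacterial flagellin that plants perceive as a sign of infection. Plants were grown for 5 weeks at 20 C with 8 h light and 16 h dark. Leaf discs of wild type were sampled at 0 h, and at 1 h and 2 h after flg22 (100 nM), an inactive flg22 from Agrobacterium tumefaciens (100 nM), the synthetic auxin NAA (10 uM), or NAA plus flg22. Leaf discs of 2 transgenic lines were sampled at 0 h and at 1 h and 2 h after flg22. The line 35S:AFB1 overexpresses an auxin receptor, and 35S:miR393 overexpresses a microRNA that targets auxin receptor transcripts. Each of the 15 groups had 3 arrays, 45 in all.

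On 43 of the arrays the lower quartile lay between 4.76 and 4.99 on the log2 scale, and the mean between 7.01 and 7.08. The other 2 arrays stood apart: wild type 0 h replicate 2 had a lower quartile of 5.79 and a mean of 7.70, and wild type flg22 2 h replicate 2 had 5.79 and 7.68. Their mean correlation with the other arrays of their own group, across probe sets, was 0.950 and 0.945, against 0.962 to 0.991 for the rest. The median residual SD was 0.275 over all 45 arrays and 0.189 over the 43. These arrays belong to groups used as controls below, so counts of changed probe sets are also given over the 43 arrays. Where a group mean lay below the lower quartile of every array, further changes may go unseen, and the size and rank of a difference are uncertain. Below, this applies to AT3G15720 with flg22 in all lines, AT2G45340 with flg22 at 1 h, AT5G22530 with inactive flg22 at 2 h, GH3.3, SAUR10 and IAA30 with inactive flg22, AT1G52560, AT1G71530 and AT5G25920 with NAA plus flg22 at 2 h, SAUR10 and AT5G50335 in the interaction, and 2 unnamed probe sets (5.43 in 35S:AFB1 at 1 h and -1.13 in 35S:miR393 at 2 h).

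**Figure D1:**
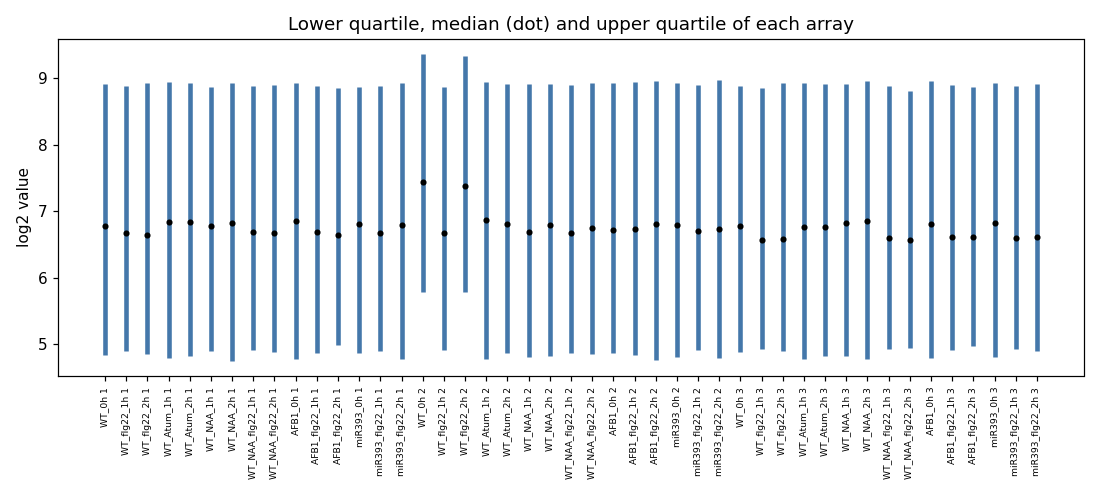
Lower quartile, median (dot) and upper quartile of the log2 values of each of the 45 arrays, with groups and replicates along the horizontal axis (WT, wild type; Atum, inactive flg22). Lower quartiles were 4.76 to 4.99 on 43 arrays and 5.79 on wild type 0 h replicate 2 and wild type flg22 2 h replicate 2.

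The first comparison asked what flg22 changed at 1 h beyond the inactive peptide. The cell wall and phenylpropanoid genes XTH18, a xyloglucan endotransglucosylase/hydrolase, and CCR2, a cinnamoyl-CoA reductase, were among the 8 largest rises. CCR2 had a log2 value of 10.86 ± 0.44 with flg22 and 6.01 ± 0.43 with inactive flg22 (SD, n = 3), a difference of 4.85 (SE 0.56, 28.8-fold, adjusted p = 3.19e-07). XTH18 rose 23.8-fold, from 7.57 ± 0.77 to 12.14 ± 0.65 (SD, n = 3, adjusted p = 1.31e-05). HMT-1, a homocysteine methyltransferase, rose by 4.47 (SE 0.42, adjusted p = 1.34e-08), and AT5G28610 rose most, by 5.15 (SE 0.55, adjusted p = 1.14e-07). The other large rises were AT1G56060 (4.98), AT1G14550 (4.68), AT5G05300 (4.59) and AT3G02840 (4.54). The largest falls were AT3G19850 (-3.81), AT3G15720 (-3.35), AT1G02300 (-3.16), AT4G01410 (-3.03), AT5G03230 (-3.03), AT2G45340 (-2.94), AT1G60010 (-2.80) and AT3G13672 (-2.78); the flg22 means of AT3G15720 (4.28) and AT2G45340 (4.72) were low in the sense above.

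Of the list of early flg22 response genes, 8 of 9 measured members rose at 1 h, and 9 did when adjusted over the list alone. They included the transcription factor genes WRKY6 (2.68, SE 0.36) and WRKY22 (2.00, SE 0.44), the U-box ubiquitin ligase genes PUB23 (3.03), PUB24 (2.26) and PUB22 (1.77), the receptor-like cytoplasmic kinase gene BIK1 (1.68), the zinc finger gene ZAT10 (1.81) and the oxidoreductase gene FOX1 (3.74). WRKY53 had 1.12 (adjusted p = 0.102). The list stood above other probe sets by camera (adjusted p = 3.99e-09), but this was lost with an estimated correlation: adjusted p = 0.0660 with an estimated correlation. Of the auxin response list, 1 of 10 members, the homeobox gene HAT2, fell by 1.33 (adjusted p = 0.0113), also when adjusted over the list alone. Over the 43 arrays 1 member of that list rose and 1 fell.

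At 1 h, 4392 of 22746 probe sets changed with flg22 against the inactive peptide, 1863 higher and 2529 lower; 1195 rose and 1058 fell at least 2-fold. The groups did not overlap for 48.6% of probe sets, where chance gives 10%. Over the 43 arrays 7766 changed, 3506 higher and 4260 lower, including all 4392. After cyclic loess scaling 2961 were higher and 2620 lower. Without wild type flg22 1 h replicate 3 the count was 2769, and without inactive flg22 1 h replicate 1 it was 2819; array weights gave 10340.

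At 2 h, AT1G14550 (3.99), CCR2 (3.89) and Hop3 (3.87) had the largest rises. Hop3, a co-chaperone gene, went from 5.82 ± 0.42 with inactive flg22 to 9.70 ± 0.20 with flg22 (SD, n = 3; SE of the difference 0.73, adjusted p = 2.09e-04). AT4G28420 (3.87), AT4G15120 (3.72), AT5G37490 (3.63), AT1G26410 (3.63) and AT5G22530 (3.56) followed. The largest falls were AT3G32930 (-3.61), AT4G32340 (-3.58), AT5G62360 (-3.34), AT2G28200 (-3.09), AT3G50270 (-3.04), AT3G15720 (-3.02), AT5G47330 (-2.94) and AT5G52960 (-2.94). AT3G32930 had -2.46 and AT5G52960 -1.74 over the 43 arrays, both past the threshold.

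All 9 measured early flg22 response genes rose at 2 h, also when adjusted over the list alone, with FOX1 at 3.31 (SE 0.84), PUB23 at 2.18 (SE 0.55) and WRKY53 at 1.58 (SE 0.48). By camera the adjusted p was 0.00161, and this call was lost: adjusted p = 0.267 with an estimated correlation. Of the photosynthesis list, the light-harvesting genes LHCB4.2 (-1.66, SE 0.38, adjusted p = 0.00155) and LHCB4.1 (-0.69, SE 0.19, adjusted p = 0.00520) fell. RCA, the Rubisco activase, had -0.22 (adjusted p = 0.120; -0.37 and past the threshold over the 43 arrays). The list as a whole stood below other probe sets by camera (adjusted p = 0.00271; adjusted p = 0.177 with an estimated correlation), and 2 of 3 fell when adjusted over the list alone. HAT2 fell by 1.18 (adjusted p = 0.0171; -1.81 over the 43 arrays), the 1 of 10 auxin response genes past the threshold at 2 h, also adjusted over the list alone. Over the 43 arrays 2 of the 10 fell and 0 rose. The median of the auxin response list was 0.36 (0.01 over the 43 arrays) and its mean 0.17, while camera, which is relative to all other probe sets, placed it below them (adjusted p = 0.853).

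Smaller lists held few measured genes. IGPS of tryptophan biosynthesis rose by 0.86 at both times (adjusted p = 0.0162 and 0.0117). UGT74B1 of indole glucosinolate synthesis rose by 1.12 at 1 h (adjusted p = 0.0235); at 2 h it had 0.73 (adjusted p = 0.102), and it was past the threshold at 2 h when adjusted over the list alone and over the 43 arrays (1.10). Of the salicylic acid list, SAG101 rose by 1.11 and 0.76, while GRX480 had 1.78 and 1.98 with adjusted p = 0.187 and 0.0898; adjusted over the list alone, GRX480 passed at 2 h. Of the abscisic acid list, the dehydrin gene COR47 had -0.86 at 1 h (adjusted p = 0.0675; past the threshold adjusted over the list alone) and fell by 1.19 at 2 h (adjusted p = 0.00739), and COR15A did not pass. The measured genes of the aliphatic glucosinolate (BCAT4, UGT74C1), jasmonate (PDF1.2a), cytokinin type-A regulators (ARR15, ARR16), flavonoid (DFR), circadian clock (GI) and guard cell markers (FAMA) lists did not pass at 1 h or 2 h, adjusted over all probe sets or adjusted over the list alone; UGT74C1 fell at 2 h over the 43 arrays (-0.73, adjusted p = 0.0282).

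In all, 7363 probe sets changed at 2 h, 5087 higher and 2276 lower; 1773 rose and 1176 fell at least 2-fold. The groups did not overlap for 34.3% of probe sets, where chance gives 10%. All probe sets had a median difference of 0.29 here, and of -0.01 after cyclic loess, which gave 3626 higher and 4031 lower. In the fit on 43 arrays 8524 changed, 4085 higher and 4439 lower. In all, 5901 probe sets were called in both fits, all in the same direction. Of those called over 45 arrays, 2 had the opposite sign over the 43, where they were not called. Without inactive flg22 2 h replicate 1 the count was 4677, and on the arrays of the compared groups alone it was 1572. Of the probe sets called at 1 h and 2 h, 1635 rose at both times, 1134 fell at both and 8 went in opposite directions; 417 and 253 shared rises and falls would be expected from the counts alone. With 43 arrays these were 2128, 2827 and 21.

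**Figure D2:**
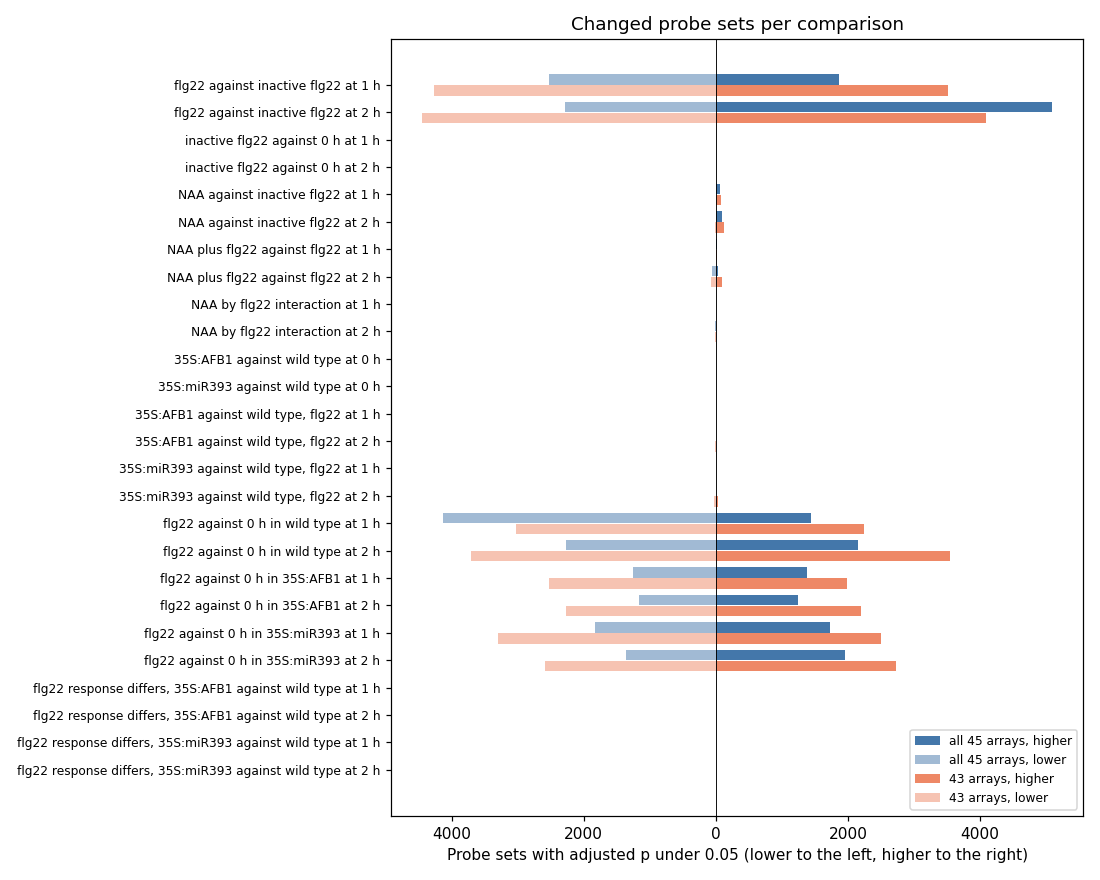
Number of probe sets past adjusted p of 0.05 in each comparison (horizontal axis; lower to the left, higher to the right), over all 45 arrays and over 43 arrays without the 2 that stood apart. At 2 h flg22 against inactive flg22 had 5087 higher and 2276 lower over 45 arrays, and 4085 higher and 4439 lower over 43.

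The inactive peptide against 0 h gave the background of the treatment itself. At 1 h, FOX1 had -0.77 (SE 0.84, adjusted p = 0.594), PUB23 -0.26 (SE 0.55, adjusted p = 0.806) and WRKY6 -0.36 (SE 0.36, adjusted p = 0.562). At 2 h, WRKY53 had 0.55 (SE 0.48, adjusted p = 0.492), WRKY6 0.41 and PUB23 0.29. No early flg22 response gene passed at either time, also when adjusted over the list alone. By camera the early flg22 response list stood above other probe sets at 2 h (adjusted p = 3.13e-05), which was lost: adjusted p = 0.268 with an estimated correlation. limma called 0 probe sets at 1 h and 0 at 2 h; 4636 and 3089 had an unadjusted p under 0.05, and 740 and 930 over the 43 arrays, which also gave 0 calls. The median of all probe sets was -0.25 at both times. Without wild type 0 h replicate 1, 3993 probe sets were called at 1 h, 288 of them higher. That fit kept replicate 2, which stood apart. Without replicate 2 the count at 1 h was 0, as it was without replicate 3. Without wild type 0 h replicate 3, 2 were called at 2 h, and array weights gave 4 at 2 h.

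NAA was compared with inactive flg22 to find auxin-regulated genes in these leaves; the NAA groups received no peptide. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, rose most at 1 h, from 4.64 ± 0.53 to 12.81 ± 0.21 (SD, n = 3), a difference of 8.18 (SE 0.45, adjusted p = 1.09e-14). Its mean with inactive flg22 lay below the lower quartile of every array, so no fold is given. HAT2 rose from 9.07 ± 0.20 to 12.83 ± 0.33 (SD, n = 3), by 3.77 (SE 0.38, 13.6-fold, adjusted p = 4.87e-08). GH3.5 (2.53), AT3G50340 (3.13), AT5G62280 (2.70), AT5G41400 (2.65), AT1G32690 (2.44) and ATIM (2.43) rose as well. Of the auxin response list 6 of 10 measured genes rose, and 7 did when adjusted over the list alone; besides GH3.3, HAT2 and GH3.5 these were IAA29 (2.37), an Aux/IAA gene, LBD16 (1.47) and SAUR10 (1.28), with IAA30 (0.70, adjusted p = 0.413) the addition. By camera the list stood above other probe sets with adjusted p = 6.76e-46, and adjusted p = 2.27e-06 with an estimated correlation.

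At 2 h, GH3.3 was higher with NAA by 8.87 (SE 0.45, adjusted p = 8.81e-16), again from a low control mean (4.32), and IAA29 rose from 4.80 ± 0.16 to 9.39 ± 0.50 (SD, n = 3), by 4.59 (SE 0.25, adjusted p = 1.70e-15). AT5G62280 (4.25), HAT2 (3.80), AT3G50340 (3.79), ATIM (3.63), SAUR10 (2.93, from a low mean of 3.56, so of uncertain size and rank) and GH3.5 (2.84) completed the 8 largest rises. Of the auxin response list 7 of 10 rose, also 7 when adjusted over the list alone, with LBD16 at 1.64 and IAA30 at 1.63; IAA20, GH3.1 and LBD29 did not pass. By camera the adjusted p was 1.19e-105, and adjusted p = 3.99e-10 with an estimated correlation. The 1 named fall was AT1G29090 (-1.80, SE 0.29, adjusted p = 2.45e-04). The early flg22 response list stood above other probe sets with NAA at 1 h by camera (adjusted p = 1.32e-08, and adjusted p = 0.0437 with an estimated correlation). However, 0 of its 9 members passed, also adjusted over the list alone. Over the 43 arrays this camera call held with the preset correlation (adjusted p = 8.54e-06). There it was lost with an estimated correlation (adjusted p = 0.128 by camera). In a principal component analysis of the 43 arrays, the first component held 53.1% of the variance. On it NAA 1 h replicates 1, 2 and 3 had -45.76, -2.14 and -41.96. Inactive flg22 at 1 h had -71.86, -59.41 and -30.01, and wild type flg22 at 1 h 39.31, 37.93 and 64.02. NAA 1 h replicate 2 thus lay nearer the flg22 arrays than replicates 1 and 3. Whether the list call rests on this array was not tested.

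At 1 h, 59 probe sets were higher with NAA and 0 lower, and 81 were higher over the 43 arrays; without NAA 1 h replicate 1 the count was 36, and on the arrays of the compared groups alone 19. At 2 h, 91 changed, 88 higher and 3 lower, and 133 over the 43 arrays, 124 higher and 9 lower; on the arrays of the compared groups alone there were 55. In all, 53 probe sets were higher at both times, where 0.23 would be expected, and 71 over the 43 arrays. Array weights gave 116 at 1 h and 180 at 2 h. With wild type 0 h as the control, which holds an array that stood apart, 40 changed at 1 h, 38 higher and 2 lower. At 2 h 75 changed against that control, 67 higher and 8 lower.

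**Figure D3:**
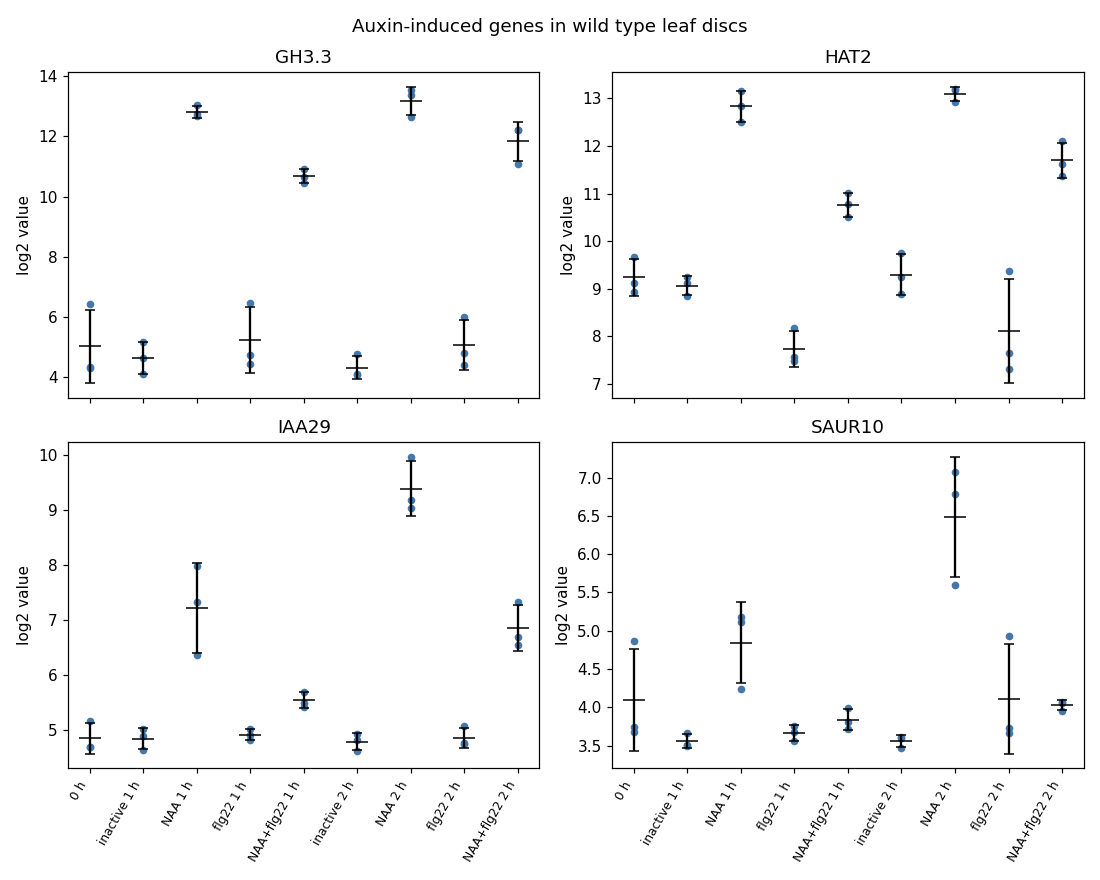
Log2 value of GH3.3, HAT2, IAA29 and SAUR10 on each array (points) in the 9 wild type groups, with the mean and SD of 3 arrays (horizontal and vertical bars). At 2 h IAA29 had a mean of 9.39 with NAA and 6.86 with NAA plus flg22, and SAUR10 had 6.49 and 4.03.

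NAA plus flg22 against flg22 asked what auxin changed in leaves that also received flg22. At 1 h GH3.3 rose from 5.23 ± 1.09 to 10.68 ± 0.24 (SD, n = 3), by 5.45 (SE 0.45, adjusted p = 8.93e-10), and HAT2 rose by 3.02 (SE 0.38, adjusted p = 7.33e-06). AT1G67340 (1.94), AT3G50340 (1.76) and AT1G32690 (1.48) rose as well. At 2 h GH3.3 rose by 6.77 (SE 0.45, adjusted p = 1.72e-12), HAT2 by 3.59, AT5G62280 by 3.58 and IAA29 by 2.00 (SE 0.25, from 4.86 ± 0.18 to 6.86 ± 0.42, SD, n = 3). AT4G09890 (2.08), AT3G50340 (2.05) and AT1G32690 (1.68) rose, as did AT5G52960 (2.13), which had 0.93 over the 43 arrays (adjusted p = 0.0862). The largest falls were AT1G52560 (-2.69), AT2G34810 (-1.72), AT1G29090 (-1.56), AT1G71530 (-1.41), AT5G25920 (-1.39), AR791 (-1.32), AT3G14200 (-1.20) and AT2G17850 (-1.15). AT1G29090 and AT5G25920 remained past the threshold over the 43 arrays (adjusted p = 0.0383 and 0.0279), and the other 6 had adjusted p from 0.0609 to 0.102.

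Of the auxin response list 2 of 10 rose at 1 h (GH3.3, HAT2) and 3 at 2 h (GH3.3, HAT2, IAA29); adjusted over the list alone it was 4 at each time, and over the 43 arrays 2 and 6. By camera the list stood above other probe sets at 1 h (adjusted p = 7.83e-41; adjusted p = 6.28e-06 with an estimated correlation) and at 2 h (adjusted p = 9.14e-16; adjusted p = 0.00389 with an estimated correlation). The photosynthesis list stood above them at 2 h (adjusted p = 0.0181; adjusted p = 0.187 with an estimated correlation), with 0 of 3 members passing. The list of early flg22 response genes had 0 of 9 past the threshold at 1 h and at 2 h, and 1 lower at 2 h when adjusted over the list alone, as was 1 of 2 salicylic acid genes.

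At 1 h 15 probe sets were higher with NAA plus flg22 and 0 lower, and 19 were higher over the 43 arrays. At 2 h 98 changed, 37 higher and 61 lower; over the 43 arrays 161 changed, 94 higher and 67 lower, with 59 probe sets called in both fits. All probe sets had a median of -0.25 at 2 h, and cyclic loess gave 63 higher and 10 lower. Single arrays moved the 2 h count: 21, 18 and 25 without NAA plus flg22 2 h replicates 1, 2 and 3, and 61 and 1694 without wild type flg22 2 h replicates 2 and 3. On the arrays of the compared groups alone it was 2, with array weights 579, and with a block for replicate number 374, 66 higher and 308 lower. At 1 h array weights gave 27.

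The interaction asked whether the NAA effect differed between leaves with and without flg22. At 2 h SAUR10 rose by 2.93 with NAA alone and had -0.08 with flg22, an interaction of -3.01 (SE 0.41, adjusted p = 1.94e-04). Its means with inactive flg22 (3.56), flg22 (4.11) and NAA plus flg22 (4.03) lay below the lower quartile of every array, where changes may go unseen, so the size of this interaction is uncertain. IAA29 had 4.59 and 2.00, an interaction of -2.59 (SE 0.35, adjusted p = 1.94e-04). AT5G50335 (-2.12, SE 0.31, adjusted p = 6.44e-04), the transcription factor gene BZIP61 (-1.92, SE 0.38, adjusted p = 0.0251) and AT5G52890 (-1.83, SE 0.33, adjusted p = 0.0105) also had smaller NAA effects with flg22, AT5G50335 from similarly low means with flg22 (3.46) and NAA plus flg22 (3.62). BZIP61 had -1.59 over the 43 arrays (adjusted p = 0.142). GH3.3 had an interaction of -2.73 at 1 h (adjusted p = 0.562; 0.0489 over the 43 arrays) and -2.10 at 2 h (adjusted p = 0.806), and HAT2 -0.74 and -0.22; HAT2 at 2 h had 0.41 over the 43 arrays.

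The auxin response list as a group responded less to NAA with flg22. Its mean NAA effect at 2 h was 2.67 alone and 1.32 with flg22, and the mean interaction of -1.35 was below 0 in 10 of 10 genes (two-sided permutation p = 0.00216, the smallest the 369600 arrangements can give; the residuals of a fit without the interaction were permuted over the 12 arrays). Without wild type flg22 2 h replicate 2 the mean was -0.93, below 0 in 7 of 10 genes (permutation p = 0.00346). At 1 h the mean was -0.94, below 0 in 9 of 10 genes (permutation p = 0.00216). By camera the list stood below other probe sets at 1 h (adjusted p = 2.12e-17; adjusted p = 0.00232 with an estimated correlation) and at 2 h (adjusted p = 7.95e-14; adjusted p = 0.00736 with an estimated correlation). At 1 h 0 of 10 passed over all probe sets and 4 when adjusted over the list alone; at 2 h 2 fell, and 6 when adjusted over the list alone.

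The 59 probe sets higher with NAA at 1 h served as a wider set for 2 h. Their mean NAA effect at 2 h was 2.68 alone and 1.39 with flg22, and 57 of 59 had a smaller effect with flg22 (mean -1.29, permutation p = 0.00216). They were picked by their response without flg22, which the auxin response list was not.

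In limma 14 probe sets had an interaction at 2 h, all lower, and 1127 an unadjusted p under 0.05; 5 of the 14 named 1 gene. With 43 arrays it was 15, all lower, with 13 in both fits. The median of all probe sets was -0.22. Left-out arrays gave 7 (inactive flg22 2 h replicate 1), 8 (replicate 2) and 9 (replicate 3), 8 and 22 (NAA 2 h replicates 1 and 2), 8 (NAA plus flg22 2 h replicates 1 and 3), and 7 and 25 (wild type flg22 2 h replicates 2 and 3). Without dim probe sets it was 7, on the arrays of the compared groups alone 0, and with array weights 30. At 1 h limma called 0, with 136 at an unadjusted p under 0.05, 4 over the 43 arrays, 3 after cyclic loess, 10 with array weights, 1 on the arrays of the compared groups alone, and 3 without NAA 1 h replicate 2.

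**Figure D4:**
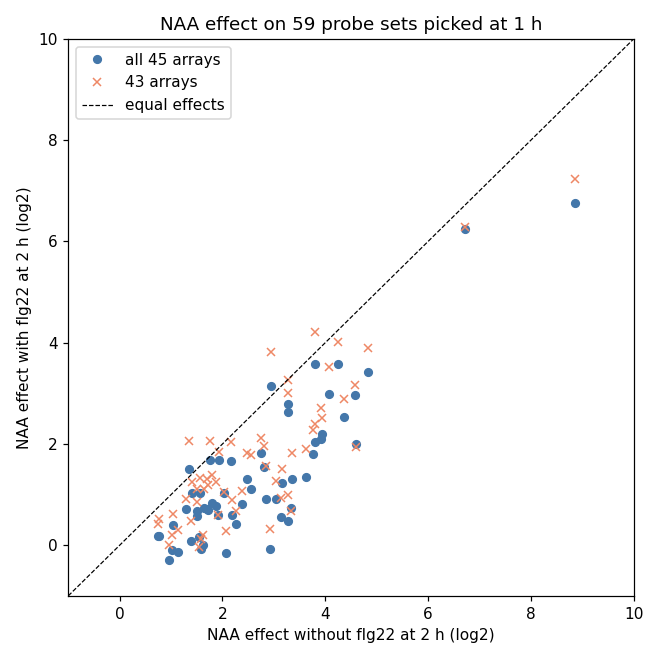
NAA effect (log2 difference) at 2 h with flg22 (vertical axis) against that without flg22 (horizontal axis) for 59 probe sets higher with NAA at 1 h, over 45 and over 43 arrays, with a dashed line of equal effects. Over 45 arrays 57 of 59 lay below the line, and the means were 1.39 with flg22 and 2.68 without.

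The comparison of 35S:AFB1 with wild type asked what the receptor transgene changed. A single probe set, which the annotation used here does not name, was higher in 35S:AFB1 in all 3 conditions. At 0 h it had 10.06 ± 0.39 in the line and 5.33 ± 0.74 in wild type (SD, n = 3), a difference of 4.74 (SE 0.30, adjusted p = 4.27e-13). With flg22 it was higher by 5.43 at 1 h (adjusted p = 6.32e-15) and by 4.85 at 2 h (adjusted p = 2.04e-13). Of 2 other unnamed probe sets that were lower in all 3 conditions, the first had -1.05, -1.14 and -1.04 at 0 h, 1 h and 2 h, and the second had -1.05 at 0 h and -1.25 at 2 h. The second did not pass at 0 h over the 43 arrays (adjusted p = 0.0722), and a further unnamed probe set was lower at 0 h only (-0.88). These probe sets were chosen after their values were seen. At 2 h AT1G78460 (1.95, SE 0.34, adjusted p = 0.00888), AT5G62360 (2.52, SE 0.50, adjusted p = 0.0467) and 2 unnamed probe sets (3.25 and 2.25) were also higher than in wild type. In the fit on 43 arrays the first 3 of these had adjusted p = 0.106, 0.132 and 0.193.

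In 35S:AFB1 against wild type 4 probe sets changed at 0 h (1 higher and 3 lower; 3 over the 43 arrays, and 2 higher and 0 lower after cyclic loess), 3 at 1 h with flg22 (1 higher and 2 lower; 5 over the 43 arrays) and 7 at 2 h with flg22 (5 higher and 2 lower; 12 over the 43 arrays, 2 higher and 10 lower, 4 in both fits). The median of all probe sets was -0.25 at 0 h and -0.23 at 2 h. The 0 h count was 1 without 35S:AFB1 0 h replicate 2 and 13 without wild type 0 h replicate 3. The 2 h count was 44, 4 and 654 without wild type flg22 2 h replicates 1, 2 and 3, and 27, 4 and 4 without 35S:AFB1 flg22 2 h replicates 1, 2 and 3. With a block for replicate number the counts were 7 at 0 h and 30 at 2 h, with array weights 8 at 1 h, and on the arrays of the compared groups alone 1 at each time. By camera the early flg22 response list stood above other probe sets at 0 h (adjusted p = 0.00932; adjusted p = 0.372 with an estimated correlation) and the photosynthesis list at 2 h (adjusted p = 0.00309; adjusted p = 0.143 with an estimated correlation).

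In 35S:miR393 against wild type with flg22 at 2 h, AT5G62360 was higher, at 11.60 ± 0.57 against 8.72 ± 0.63 (SD, n = 3), a difference of 2.89 (SE 0.50, adjusted p = 0.0123). AT1G78460 was higher by 2.11 (SE 0.34, adjusted p = 0.00538) and AT2G29065 lower, at 6.65 ± 0.04 against 7.82 ± 0.09 (SD, n = 3, adjusted p = 0.0303). These 3 genes also passed over the 43 arrays (adjusted p = 0.0352, 0.0317 and 0.0202). Among unnamed probe sets 4 were higher, by up to 10.5-fold, and 3 lower (-1.23, -1.13 and -0.82); the largest rise and the largest fall of these did not pass over the 43 arrays (adjusted p = 0.0621 and 0.0576). The unnamed probe set that was higher in 35S:AFB1 in all 3 conditions did not pass in this line (-0.43, -0.08 and -0.55 at 0 h, 1 h and 2 h). AT5G62360 and the unnamed probe set with the largest rise were lower in wild type at 2 h with flg22 than with inactive flg22 (-3.34 and -4.10).

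limma called 0 probe sets in 35S:miR393 against wild type at 0 h (3251 at an unadjusted p under 0.05; 386, and 0 calls, over the 43 arrays) and 0 at 1 h with flg22 (164; 665, and 0 calls, over the 43 arrays). At 2 h 10 changed, 6 higher and 4 lower; over the 43 arrays 66 changed, 37 higher and 29 lower, with 8 in both fits, and cyclic loess gave 7 higher and 1 lower. The median of all probe sets was -0.25 at 0 h and -0.26 at 2 h. The 2 h count was 3971 (214 higher) and 3201 (229 higher) without wild type flg22 2 h replicates 1 and 3. Both fits kept replicate 2, which stood apart, and without it the count was 12. Without 35S:miR393 flg22 2 h replicates 1, 2 and 3 the count was 0, 3 and 5. It was 232 with a block for replicate number (48 higher and 184 lower), 877 with array weights and 0 on the arrays of the compared groups alone. By camera the photosynthesis list stood above other probe sets at 2 h (adjusted p = 5.18e-04; adjusted p = 0.0744 with an estimated correlation) and at 0 h (adjusted p = 0.0446; adjusted p = 0.408 with an estimated correlation). Adjusted over the list alone, DFR was higher and UGT74B1 lower at 0 h, and PDF1.2a higher and GH3.5 lower at 2 h. DFR, UGT74B1 and PDF1.2a are each the only measured gene of their list, so theirs are unadjusted p-values, and over the 43 arrays UGT74B1 had -0.15 instead of -0.74 and GH3.5 -0.72 instead of -1.38.

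The last comparisons set flg22 against 0 h in each line. At 1 h AT5G28610 rose by 4.97 in wild type, 4.67 in 35S:AFB1 and 4.59 in 35S:miR393 (SE 0.55, n = 3 each), and CCR2 rose by 3.67, 4.25 and 4.74 (SE 0.56, n = 3 each). HMT-1 was among the 8 largest rises in wild type (3.64) and 35S:miR393 (4.57), and AT1G14550 in 35S:AFB1 (4.39) and 35S:miR393 (4.56). AT3G15720 fell in wild type, 35S:AFB1 and 35S:miR393 (-3.29, -2.63, -3.26), as did AT3G19850 (-3.84, -2.35, -2.84). At 2 h AT1G36640 rose by 2.96, 3.51 and 4.43, AT3G15720 fell (-2.91, -2.85, -2.91), and AT1G14550 rose by 4.87 in 35S:AFB1 and 5.04 in 35S:miR393. CRR42, needed for the chloroplast NDH complex, fell in wild type at 2 h (-2.88, SE 0.56, adjusted p = 7.93e-04).

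Of the early flg22 response genes all 9 rose in wild type at 1 h and at 2 h. In 35S:AFB1 8 rose at 1 h and 7 at 2 h, and in 35S:miR393 8 and 9; adjusted over the list alone it was 9 in each line at each time. PUB23 rose by 2.77, 2.70 and 3.17 at 1 h in wild type, 35S:AFB1 and 35S:miR393 (SE 0.55, n = 3 each), and WRKY6 by 2.32, 2.15 and 3.05 (SE 0.36, n = 3 each). By camera the list stood above other probe sets in each line at each time. Over 45 arrays that held with an estimated correlation in wild type at 1 h (0.0210), 35S:AFB1 at 1 h (0.0408) and 35S:miR393 at 1 h and 2 h (0.0270 and 0.0393). It was lost in wild type at 2 h (adjusted p = 0.0673 with an estimated correlation) and in 35S:AFB1 at 2 h (adjusted p = 0.0949 with an estimated correlation). Over the 43 arrays the calls that held were lost as well. In the same order their adjusted p by camera was 0.113, 0.115, 0.0874 and 0.105 with an estimated correlation. At 2 h UGT74B1 and IGPS rose and COR47 fell in all 3 lines. In wild type, 35S:AFB1 and 35S:miR393 over the 43 arrays UGT74B1 had 2.15, 2.06 and 2.32, IGPS 1.63, 1.40 and 1.60, and COR47 -1.66, -1.62 and -1.43; over all 45 arrays wild type had 1.197, 0.96 and -1.05 for these 3 genes.

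**Figure D5:**
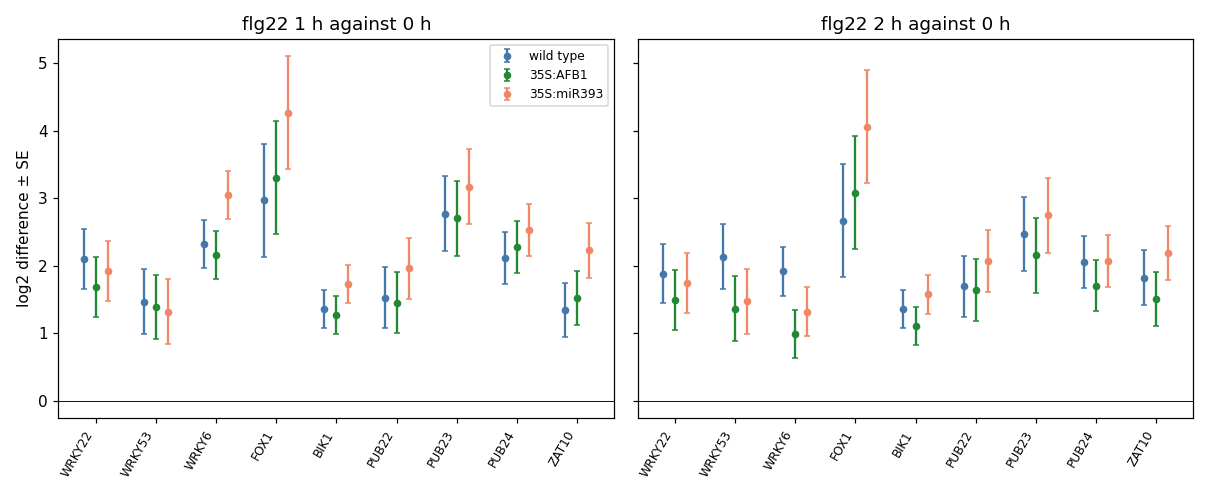
Log2 difference of flg22 against 0 h (vertical axis, mean with SE of the fit, n = 3) for the 9 measured early flg22 response genes in wild type, 35S:AFB1 and 35S:miR393 at 1 h (left) and 2 h (right). PUB23 at 1 h had 2.77, 2.70 and 3.17 in the 3 lines.

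In wild type 5560 probe sets changed at 1 h, 1437 higher and 4123 lower (over the 43 arrays 5267, 2239 higher and 3028 lower; after cyclic loess 2847 higher and 2327 lower; the median of all probe sets was -0.27), and 4405 at 2 h, 2144 higher and 2261 lower (7249 over the 43 arrays, 8007 with array weights). On the arrays of the compared groups alone the wild type counts were 1827 at 1 h and 14 at 2 h, and 5 of the 10 splits of the 6 arrays at 2 h, the real one included, gave at least 4405. In 35S:AFB1 it was 2635 at 1 h (1385 higher, 1250 lower) and 2395 at 2 h (1237 higher, 1158 lower). Over the 43 arrays it was 4507 (1988 higher, 2519 lower) and 4472 (2200 higher, 2272 lower), so the balance turned at both times. In 35S:miR393 it was 3549 (1726 higher, 1823 lower) and 3311 (1948 higher, 1363 lower), and 5797 and 5317 over the 43 arrays. At 1 h 1122 probe sets rose and 1082 fell in all 3 lines, and at 2 h 1048 rose and 672 fell (1633 and 2005, and 1693 and 1640, over the 43 arrays); over 45 arrays 0 were called in opposite directions in any pair of lines, and the differences correlated across probe sets, which are not independent replicates, with r from 0.843 to 0.956.

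These counts moved with single arrays and with the fit. Array weights gave 6280 (2692 higher, 3588 lower) and 8179 in 35S:AFB1 and 6748 and 7335 (3509 higher, 3826 lower) in 35S:miR393; in 35S:AFB1 at 1 h a block for replicate number gave 1662 higher and 1914 lower; in 35S:AFB1 at 2 h a block for replicate number gave 3602 and the arrays of the compared groups alone 446. In wild type at 2 h they were 2572, 7857 and 2076 without flg22 2 h replicates 1, 2 and 3, and 7449 without 0 h replicate 2. In 35S:AFB1 at 1 h they were 1682 and 1239 without flg22 1 h replicates 1 and 3, and 1291 without 0 h replicate 3; at 2 h 843, 3849 and 473 without flg22 2 h replicates 1, 2 and 3, and 1265 and 691 without 0 h replicates 1 and 3. In 35S:miR393 at 1 h they were 2360 and 2168 without 0 h replicates 1 and 3 and 2282 without flg22 1 h replicate 3; at 2 h 1651 and 1956 without 0 h replicates 1 and 3 and 1542 without flg22 2 h replicate 3.

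Whether a line responded differently to flg22 was tested by the difference of its response from that of wild type. FOX1, PUB23, WRKY6 and the other early flg22 response genes did not pass in either line at 1 h or 2 h, also adjusted over the list alone. By camera that list stood below other probe sets in 35S:AFB1 at 1 h (adjusted p = 0.0134), which was lost: adjusted p = 0.7995 with an estimated correlation, and adjusted p = 0.126 with the preset correlation over the 43 arrays. At 2 h in 35S:AFB1 the list did not pass over 45 arrays (adjusted p = 0.0547) and stood below other probe sets over the 43 (adjusted p = 0.00601, preset correlation, median -0.71), with 0 of 9 members passing in either fit. That was lost over the same 43 arrays (adjusted p = 0.352 with an estimated correlation; 0.5815 over 45). On the first principal component given above, 35S:AFB1 flg22 2 h replicates 1, 2 and 3 had 55.61, -3.33 and 57.21. Wild type flg22 2 h replicates 1 and 3 had 64.57 and 75.27. In 35S:AFB1 at 0 h replicates 1, 2 and 3 had -49.52, -17.42 and -56.87. Whether the shift of the list rests on 35S:AFB1 flg22 2 h replicate 2 was not tested. The photosynthesis list stood above other probe sets at 2 h only over the 43 arrays, with 0 of 3 members passing (adjusted p = 0.0148 in 35S:AFB1 and 0.00119 in 35S:miR393, preset correlation). Both were lost over the 43 arrays (adjusted p = 0.3496 with an estimated correlation, and adjusted p = 0.1035 with an estimated correlation; 0.5815 and 0.522 over 45). Adjusted over the list alone, 1 of 2 salicylic acid genes responded less in 35S:AFB1 at each time (medians of the list -0.73 and -1.07, and -0.64 and -1.17 over the 43 arrays). In 35S:miR393 at 2 h UGT74B1 was higher (1.12, but 0.16 over the 43 arrays) and DFR lower (-1.57, and -1.33 over the 43 arrays) by this measure, which is the unadjusted p for these 2 lists of 1 measured gene. limma called 0 probe sets in 35S:AFB1 at 1 h and 2 h and in 35S:miR393 at 1 h and 2 h. In that order 568, 442, 500 and 370 had an unadjusted p under 0.05, and 280, 1577, 220 and 1179 over the 43 arrays, where the calls were 0 as well; array weights gave 2 at 2 h in 35S:AFB1 and 3 at 2 h in 35S:miR393, and leaving out wild type flg22 2 h replicate 1 gave 1 in 35S:AFB1 at 2 h. The 95% confidence interval of the difference lay within 1 log2 unit of 0 for 56%, 69.8%, 56.4% and 71.2% of probe sets over 45 arrays. For these probe sets smaller differences were not excluded. For the others the interval reached beyond 1 log2 unit, so larger differences were not excluded either. The median of all probe sets was 0.25 at 1 h in both lines.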

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

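Among the tests below, those of separate processing of the 2 arrays, of the shared wild type arrays, of the array that stood apart, of saturation and of a smaller auxin response, and the simulation for the shared arrays and the splits within replicate numbers, were chosen only after the result was seen.

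Several results were singled out because a test of the difference between conditions or lines passed. With flg22 the NAA effect was smaller in 14 probe sets at 2 h, among them SAUR10 (-3.01), IAA29 (-2.59), AT5G50335 (-2.12), BZIP61 (-1.92) and AT5G52890 (-1.83); SAUR10 and AT5G50335 had means below the lower quartile of every array in both groups with flg22, so the size of theirs is uncertain. The auxin response list had a smaller NAA effect with flg22 at 1 h (adjusted p = 2.12e-17 by camera) and at 2 h (adjusted p = 7.95e-14). The early flg22 response list stood below other probe sets in the interaction at 1 h by camera (adjusted p = 1.17e-06), which was lost: adjusted p = 0.0876 with an estimated correlation, and 0 of 9 members passed. This interaction includes NAA 1 h replicate 2, which lay nearer the flg22 arrays than replicates 1 and 3 as given above. In 35S:AFB1 the early flg22 response list had a smaller response to flg22 than in wild type at 1 h relative to other probe sets (adjusted p = 0.0134), which was lost: adjusted p = 0.7995 with an estimated correlation, and 0.126 over the 43 arrays with the preset one (at 2 h 0.0547 over 45 arrays, and 0.00601 over the 43, where adjusted p = 0.352 with an estimated correlation). Its mean difference was -0.02 with 0 of 9 members passing, while the median of all probe sets was 0.25. The 2 h value over the 43 arrays includes 35S:AFB1 flg22 2 h replicate 2, which lay apart from replicates 1 and 3 as given above.

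The smaller auxin effect with flg22 at 2 h was weighed against the array that stood apart and against saturation. Low values, where changes may go unseen, were not weighed as a cause. Without dim probe sets 7 probe sets had an interaction. The lowest mean with NAA alone among the 14 was 4.63. Without the 2 arrays of another distribution 15 probe sets kept or gained an interaction, 13 of them among the 14, which argues against that array as the whole cause. The highest mean with NAA plus flg22 among the 14 probe sets was 8.16, below the 99th percentile of all values, 13.18, which argues against saturation; the level with NAA alone (up to 9.39), planned as this test, decides nothing, since saturation there would shrink the effect without flg22. The 59 probe sets picked at 1 h had a mean interaction of -0.94 at 2 h without that array (55 of 59 below 0, permutation p = 0.0013), so a smaller response of auxin-induced genes in flg22-treated leaves may account for the pattern, as a hypothesis found and tested on the same data. Of 100 splits, the real one and random permutations of the residuals of a fit without interaction, 2 gave as many as 14 probe sets, the real one included, and the highest other gave 22; with residuals permuted only within replicate numbers it was also 2 of 100, and 16, which argues against chance at this share, although 1 arrangement of each kind exceeded the real count and a fit on the compared groups alone called 0.

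The calls of 35S:miR393 against wild type with flg22 at 2 h were weighed against the shared wild type arrays: of the 10 probe sets, 100% moved the same way in both other comparisons against the same wild type flg22 2 h arrays (61 of 66, or 92.4%, over the 43 arrays). Sharing the arrays builds in part of this: in 200 simulated data sets without effects the share was 32.6% on average and at most 80%. The simulated arrays all had the same spread, so none stood apart. The state of these arrays and a change common to the other groups cannot be told apart by this share. An effect of the line stays open too: 30% (3 of 10) also differed between 35S:miR393 with flg22 and wild type with NAA plus flg22, and 19.7% (13 of 66) over the 43 arrays. The differences of the 2 lines from wild type at 2 h correlated at r = 0.871 across probe sets, where shared controls alone gave 0.499 in simulated data. An array that stood apart is among these controls, so this contrast alone decides nothing. At 0 h, where the other such array is shared, r was 0.754 over 45 arrays (simulated 0.4995) and 0.488 over the 43 (simulated 0.597). At 2 h over the 43 arrays r was 0.885 (simulated 0.601).

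The 2 arrays that stood apart were weighed against processing and RNA quality. The actin 3' minus 5' difference on wild type flg22 2 h replicate 2 was 1.26, inside the range of 0.891 to 1.32 of the other 43 arrays. This argues against RNA quality as the cause for both arrays. On wild type 0 h replicate 2 it was 1.74, outside that range. The GAPDH 3' minus 5' difference was 0.003 on wild type 0 h replicate 2 and -0.208 on wild type flg22 2 h replicate 2. Both lay inside the range of -0.304 to 0.012 of the other 43 arrays. For processing of these 2 arrays apart from the others, their deviations from the other replicates correlated at r = 0.397. The highest r for other pairs of arrays was 0.830. Both are replicate 2, and residuals of arrays with the same number had a median r of 0.344. This r cannot decide the question, since it leaves out a shift common to all probe sets. Such a shift was present and alike on both arrays. Their lower quartiles were 5.79 and 5.79 (4.76 to 4.99 on the other 43). Their means were 7.70 and 7.68 (7.01 to 7.08 on the other 43). A scale shared by only these 2 arrays goes with processing apart from the others, but the RMA settings are not known. No biological explanation was tested, since the design gives none for single replicates.

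Comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05, so only the real count and the highest of the other splits are given. For flg22 against inactive flg22 these were 4392 and 0 at 1 h and 7363 and 2039 at 2 h. For inactive flg22 against 0 h they were 0 and 1 at both times, with all 10 splits at least as high as the real one. For NAA they were 59 and 0 at 1 h and 91 and 0 at 2 h, and for NAA plus flg22 against flg22 15 and 0 at 1 h and 98 and 949 at 2 h. For 35S:AFB1 against wild type they were 4 and 0 at 0 h, 3 and 0 at 1 h, and 7 and 1203 at 2 h (5 of 10 splits as large, the real one included). For 35S:miR393 they were 0 and 0 at 0 h and 1 h, and 10 and 1046 at 2 h. For flg22 against 0 h they were 5560 and 429 at 1 h and 4405 and 13908 at 2 h (5 of 10 splits as large, the real one included) in wild type, 2635 and 0, and 2395 and 0, in 35S:AFB1, and 3549 and 0, and 3311 and 0, in 35S:miR393. For comparisons of 4 groups, with 100 such splits by permuted residuals, the interaction at 1 h had 0 and 0. Response differences had 0 in the real split and 0 and 12898 (35S:AFB1, 1 h and 2 h) and 21 and 12279 (35S:miR393) in the highest other. With a real count of 0 every split is as large, so these splits say nothing about chance. Splits with several times the real count point to a structure of the samples; in wild type at 2 h the split with 13908 put the 2 arrays that stood apart on the same side.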

How the results depend on the processing

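The fit on 43 arrays, without the 2 arrays of another distribution, was chosen after seeing the data. The balance of rises and falls turned in some counts. Over the 43 arrays flg22 at 2 h went from 5087 higher and 2276 lower to 4085 and 4439. There 2 probe sets called over 45 arrays had the opposite sign over the 43, without being called. NAA plus flg22 at 2 h went from 37 and 61 to 94 and 67, and 35S:AFB1 at 2 h from 5 and 2 to 2 and 10. In 35S:AFB1 flg22 against 0 h went from 1385 and 1250 to 1988 and 2519 at 1 h. At 2 h it went from 1237 and 1158 to 2200 and 2272. Flg22 against 0 h in 35S:AFB1 at 1 h had 1662 and 1914 with the replicate block and 2692 and 3588 with array weights. After cyclic loess flg22 had 2961 and 2620 at 1 h and 3626 and 4031 at 2 h, and flg22 against 0 h at 1 h 2847 and 2327 in wild type (main 1437 and 4123) and 2515 and 1969 in 35S:miR393. Other balances turned as well, with the block in 35S:AFB1 at 2 h (1747 and 1855), with array weights in 35S:miR393 at 2 h (3509 and 3826), and in small counts under the block, array weights, cyclic loess and the compared groups alone. Of 286 values for named genes, 163 kept their direction and side of the threshold in all settings run for them. The 26 list tests past the threshold with the preset correlation were run in fewer settings, and 19 kept theirs. They were not run on the compared groups alone, with trend and robust options or with an array left out. The mean over all probe sets of a gene checked only their direction. The estimated correlation was not among these settings, and several list calls were lost with it, as given above. Counts not given here stayed within 1.5 times the main one under the settings below; where they did not, the cause was not tested, except that fits on the compared groups alone or without an array hold fewer arrays. Without dim probe sets the interaction at 2 h had 7. With a block for replicate number, NAA plus flg22 against flg22 at 2 h had 374, and 35S:AFB1 against wild type 7 at 0 h and 30 at 2 h. With it 35S:miR393 against wild type had 232 at 2 h, and flg22 against 0 h in 35S:AFB1 3602 at 2 h. The labels do not say that the numbers pair the samples. However, 39 of 43 arrays lay nearest to arrays of their own number (median r of residuals 0.344, and -0.189 for other numbers). The permutations of list means and the splits leave this out, except the splits within replicate numbers. Within numbers 1, 2 and 3 the auxin response list had a mean interaction of -0.99, -0.85 and -0.98 at 1 h and -1.28, -1.65 and -1.11 at 2 h. On the arrays of the compared groups alone, flg22 had 1572 at 2 h, NAA 19 and 55, NAA plus flg22 2 at 2 h, the interaction 1 and 0, 35S:AFB1 1 at 0 h, 1 h and 2 h, 35S:miR393 0 at 2 h, and flg22 against 0 h 1827 and 14 in wild type and 446 in 35S:AFB1 at 2 h. With array weights, flg22 had 10340 at 1 h, inactive flg22 against 0 h 4 at 2 h, NAA 116 and 180, NAA plus flg22 27 and 579, the interaction 10 and 30, 35S:AFB1 8 at 1 h, 35S:miR393 877 at 2 h, flg22 against 0 h 8007 in wild type at 2 h, 6280 and 8179 in 35S:AFB1 and 6748 and 7335 in 35S:miR393, and the response differences 2 and 3 at 2 h. After cyclic loess the interaction at 1 h had 3 and 35S:AFB1 at 0 h 2. Over the 43 arrays flg22 had 7766 at 1 h, NAA plus flg22 161 at 2 h, the interaction at 1 h 4, 35S:AFB1 5 and 12, 35S:miR393 66, and flg22 against 0 h 7249 in wild type at 2 h, 4507 and 4472 in 35S:AFB1 and 5797 and 5317 in 35S:miR393. Leaving out 1 array at a time gave 2769 to 4254 and 4677 to 10670 for flg22, 0 to 3993 and 0 to 2 for inactive flg22 against 0 h, 36 to 50 and 68 to 90 for NAA, 11 to 13 and 18 to 1694 for NAA plus flg22, 0 to 3 and 7 to 25 for the interaction, 1 to 13, 2 to 3 and 4 to 654 for 35S:AFB1 and 0 to 3971 for 35S:miR393 at 2 h. For flg22 against 0 h at 1 h and 2 h it gave 3823 to 8184 and 2076 to 7857 in wild type, 1239 to 2837 and 473 to 3849 in 35S:AFB1, and 2168 to 3370 and 1542 to 3278 in 35S:miR393. The response difference of 35S:AFB1 at 2 h had 0 to 1, and the other counts of 0 stayed 0. A group with 1 array left out has 2 arrays, and its spread is pooled from all groups.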

Other observations

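The gene families below were chosen after their values were seen, from 161 families of gene names tested by camera. With an estimated correlation 2 families passed. The IAA family, of Aux/IAA genes, stood above other probe sets with NAA at 2 h (adjusted p = 0.00197 with an estimated correlation), with 2 of 7 measured members higher. The YCF family, of plastid open reading frames, stood below them in the response difference of 35S:miR393 from wild type at 1 h (adjusted p = 0.0211 with an estimated correlation; 0.000549 over the 43 arrays with the preset one), with a median of -0.60 and 0 of 6 members passing. It moved with the wider set of 87 organelle-encoded genes, which stood below as well (adjusted p = 2.15e-28; adjusted p = 0.180 with an estimated correlation; 9.74e-15 over the 43 arrays). At 0 h, before flg22, YCF stood above other probe sets in 35S:miR393 (adjusted p = 1.77e-04; adjusted p = 0.670 with an estimated correlation; 0.147 over the 43 arrays). The shift was not particular to this line: in the response difference of 35S:AFB1 at 1 h YCF stood below as well (adjusted p = 6.70e-06; adjusted p = 0.230 with an estimated correlation; 0.261 over the 43 arrays), as did the organelle-encoded genes (adjusted p = 5.00e-19; adjusted p = 0.781 with an estimated correlation; 1.81e-06 over the 43 arrays). In wild type with inactive flg22 against 0 h at 1 h both stood above (adjusted p = 0.0111 and 3.56e-11; adjusted p = 0.878 and 0.993 with an estimated correlation; 0.599 and 0.00764 over the 43 arrays). All of these comparisons share the wild type 0 h arrays. With flg22, 35S:miR393 against wild type does not. There YCF and the organelle-encoded genes stood below at 1 h (adjusted p = 0.0239 and 4.83e-05, 0.998 with an estimated correlation for both, 0.175 and 8.47e-04 over the 43 arrays). At 2 h both stood above (adjusted p = 0.0102 and 4.06e-06, 0.974 with an estimated correlation for both, 0.430 and 0.408 over the 43 arrays). The YCF result is not read as an effect of 35S:miR393, and such an effect is not excluded.

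Of the CRR family, genes needed for the chloroplast NDH complex or chloroplast RNA editing, 4 of 7 measured members fell with flg22 against inactive flg22 at 2 h, and 0 rose. CRR42 had 6.35 ± 1.26 with flg22 and 9.08 ± 0.55 with inactive flg22 (SD, n = 3), a difference of -2.73 (SE 0.56, adjusted p = 4.65e-04). CRR41 had -2.48 (SE 0.44), NdhS -2.01 (SE 0.45) and CRR28 -0.36 (SE 0.11). The family had adjusted p = 0.00175 with the preset correlation, and adjusted p = 0.9998 with an estimated correlation; 6 of 7 fell over the 43 arrays. At 1 h CRR41 (-1.38) and NdhS (-1.24) fell.

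Of the SEC family 8 of 12 measured members rose with flg22 at 2 h and 0 fell, and 8 rose and 1 fell over the 43 arrays. Of the UBP family, which are ubiquitin-specific proteases, 7 of 12 rose and 0 fell, and 9 rose over the 43 arrays. Neither family passed the camera test over 45 arrays (adjusted p = 0.142 and 0.291), and both did over the 43 arrays (adjusted p = 0.0248 and 0.0126); with 45 arrays adjusted p = 0.9998 with an estimated correlation for both.

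Among probe sets that the annotation used here does not name, 2 with large NAA effects were followed, chosen after their values were seen. The first rose with NAA by 6.19 at 1 h and 6.71 at 2 h (SE 0.39, n = 3), from a mean at 1 h of 4.32, below the lower quartile of every array, so of uncertain size, and with flg22 present by 5.89 and 6.25; its interaction was -0.30 and -0.46 (adjusted p = 1 and 0.821). The second rose with NAA by 4.62 and 4.83 (SE 0.30, n = 3), and with flg22 present by 3.37 and 3.42; its interaction was -1.25 and -1.41 (adjusted p = 1 and 0.806).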
